A study of Mus musculus with 24 samples.

How the data were processed

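The series holds 24 samples: 12 total RNA libraries and 12 ChIP samples of female mouse embryonic stem cells, WT and G9a knockout, at day 0 and day 10 of differentiation. There are 3 RNA libraries in each of 4 groups (RNeasy extraction, Ribo-Zero depletion) and 1 H3K9ac sample per group. The 4 H3K9me2 samples were not used here, and the 4 input samples enter only through the peak lists. For 2 inputs the title and the characteristics name different days, so they were left unassigned.

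Per the submitters' notes RNA reads were aligned with TopHat and counted with HOMER, ChIP reads were aligned with Novoalign and peaks were called with MACS2, all on mm9; no versions are given. The control used by MACS2, the strand of the RNA libraries, the placement of reads with several positions and the assignment of reads to alleles are not stated. The gene table deposited by the authors gives per gene and library a signal of reads scaled to a common total. Its comparison columns, deposited by the authors, hold log2 ratios, fold values and p-values. The allele table deposited by the authors holds read counts of the mus and cas alleles per gene and library. Per the file headers the peak lists hold fold enrichment, -log10 p-value and -log10 q-value; the lowest -log10 p listed is 2.0, so no weaker peak can be seen.

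The design had assumed counts in the gene table, but it holds scaled signal. The values of each library are whole numbers times 1 factor, and whole reads were recovered from them (100% of values whole within 0.006). The gene length given equals the genomic span in 99.79% of 24016 genes, so reads cover exons and introns. The copy number given is over 1 in 1.63% of genes.

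Comparisons were knockout against WT at day 0 and at day 10, day 10 against day 0 in WT and in knockout, and the difference of the last 2 changes. Genes were tested in R 4.3.3 with limma 3.58.1 (trend, robust) on log2 of the value plus 1, over genes above 1 in at least 3 libraries (20624 genes), with all 12 libraries in the fit and Benjamini-Hochberg adjustment at 0.05. The recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood, TMM, 14884 genes), which called 0, 0, 1046, 1046 and 0 genes in the 5 comparisons, and with DESeq2 1.42.0. Gene lists (27 fixed lists and all X-linked genes) were tested with camera from limma at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. X-linked genes were compared with other genes by Fisher's exact test. Group means were compared by exact permutation of libraries, 2-sided. Errors of means are SD, and errors of log2 changes are moderated standard errors (SE).

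Allele counts were tested with edgeR with a term for each library and group by allele terms, over genes with at least 10 allelic reads in every compared library. Shares from single libraries carry Wilson 95% intervals. A ratio against a group at 0 is given only as a bound, with a floor of 3 counts. Peak overlap, promoters (1 kb either side of the start) and matched random gene lists (10000) were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9.

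Libraries hold 2081129 to 30527844 recovered reads, and X-linked allelic reads number 12931 to 306849 per library. Within-group log2 correlations run from 0.816 to 0.993. Simulated data had the spread of these libraries (dispersion 0.26), with changes up or down placed in genes with mean scaled reads above 100. Of 100 genes changed 4-fold limma recovered 4% at day 0 and 11% at day 10, and 0% of genes changed 2-fold. For the 4-fold genes edgeR recovered 17 and 19%. With 0.1 of that dispersion both recovered 100% of the 4-fold genes. The allele test recovered 40% of genes simulated at an odds ratio of 3.

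Groups, comparisons, tests, gene lists, thresholds, the rule for which genes are named and the first set of alternatives were fixed before the data were examined. The rule names Ehmt2, Ehmt1 and 5 X-inactivation center genes in each comparison, the 10 highest and 10 lowest passing genes between knockout and WT, the 5 highest and 5 lowest of the other comparisons, and up to 4 passing members of each list. Between knockout and WT such genes had to have a mean log2 CPM above 1 and groups that do not overlap; predicted genes and noncoding fragments were passed over. Not every gene the rule names is printed.

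Alternatives fixed at that time were RLE scaling, no filter, DESeq2, only the compared groups in the fit, a fold threshold, replicate number as a block, pseudocounts of 0.1 and 5, and each library left out in turn. For lists, X-linked genes, alleles and peaks they were an estimated correlation, other read minimums, and other overlap and strength settings. After the data had been seen a depth term, edgeR on recovered reads, TMM scaling, fits without the 2 libraries with background reads, day 0 medians within depth classes, the best covered X-linked genes and chromosomes 5, 7, 9 and 13 were added. Not used here were 1 deposited comparison column outside the design and the H3K9me2 samples.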

Results

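Female mouse embryonic stem cells of the hybrid line 16.7 Tsix +/TST (parental, WT) and a knockout of the H3K9 methyltransferase G9a made in that line (KO) were compared before differentiation (day 0) and after 10 days of it (4 days in suspension, 6 days plated, without LIF). Total RNA was sequenced in 3 libraries per group (12 in all), and H3K9ac, a mark of active promoters, was mapped by ChIP in 1 sample per group. The comparisons ask what G9a does to gene activity in stem cells, what it does in differentiated cells, which genes change as each line differentiates, and whether X inactivation proceeds without G9a. Values are reads scaled by the authors to a common total per library.

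Ehmt2, the gene of the H3K9 methyltransferase G9a (chromosome 17, 35035437 to 35050995, mm9), was read in every library. The 3 parental (WT) libraries of day 0 held 986.8, 1102.3 and 1375.1 scaled reads, and the 3 knockout (KO) libraries held 557.3, 440.9 and 375.4. On day 10 of differentiation the values were 1296.9, 1358.9 and 718.6 in WT and 499.8, 758.4 and 628.3 in KO. The KO mean was 458 ± 92.1 (SD, n = 3) against 1155 ± 199 at day 0, and 629 ± 129 against 1125 ± 353 at day 10. With 3 against 3 libraries the smallest reachable exact p is 0.1, and Ehmt2 gave an exact p of 0.1 at day 0 and 0.2 at day 10. In limma over all genes its log2 fold change was -1.34 (SE 0.31, adjusted p = 0.993) at day 0 and -0.80 (SE 0.31, adjusted p = 0.323) at day 10, so neither passed; edgeR gave -1.32 (adjusted p = 0.941) and -0.79 (adjusted p = 0.303). The day 0 value was -0.90 between shallow libraries (2 WT, 1 KO) and -1.75 between deep ones (1 WT, 2 KO). Reads are counted over the whole gene body, so the deleted part of Ehmt2 cannot be seen. Ehmt1, the gene of the partner methyltransferase GLP (chromosome 2, 24646289 to 24775129), was at 0.08 and -0.23 and did not pass.

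**Figure D1:**
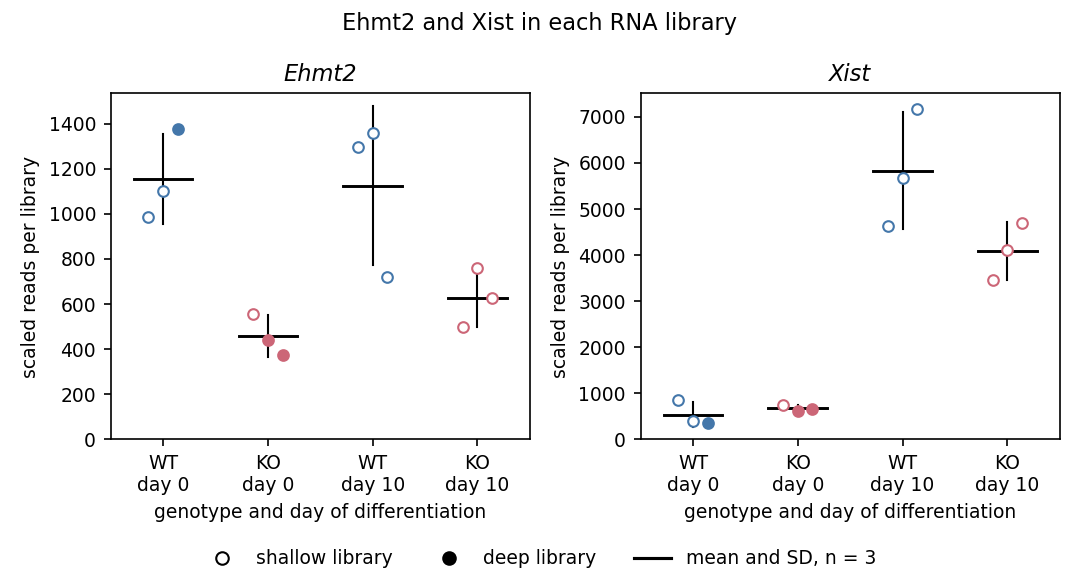
Scaled reads (linear axis) of Ehmt2 and Xist in WT and KO at day 0 and day 10; points are libraries (open shallow, filled deep), lines are means and bars are SD with n = 3. The Ehmt2 mean is lower in KO on both days (458 against 1155 and 629 against 1125), and Xist reaches 5826 in WT and 4089 in KO at day 10.

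The RNA libraries differ in depth. At day 0 WT replicate 3 and KO replicates 2 and 3 hold 30527844, 26683251 and 21087157 reads, and the other 9 libraries hold 2081129 to 4220140. Ribosomal Rn45s takes 14.8 to 25.1% of reads in the 9 shallow libraries and 0.115 to 0.129% in the deep ones. Genes of olfactory and vomeronasal receptors, which are silent in these cells, carry 1072 CPM (reads scaled to depth, without Rn45s) in KO replicate 1 of day 0 and 1093 in WT replicate 3 of day 10, against 31.1 to 377 elsewhere. Both libraries therefore hold background reads, which weigh most on long genes. Col1a1, the collagen I gene, stood at 3996.6, 91.9 and 47.8 in WT and at 924.7, 64.8 and 68.4 in KO at day 0. In the same first replicates 12 (WT) and 14 (KO) of 16 fibroblast genes were above both other libraries, and Y-linked genes had 28.3 and 11.9 CPM, against at most 3.05 elsewhere. Both are shallow libraries. The p values of limma, edgeR, DESeq2 and exact permutation measure only the spread between these samples. Fisher's exact tests of X-linked genes, random gene lists and camera at the preset correlation compare genes with other genes, so their p values do not measure that spread. The labels give each RNA library its own donor number and do not say whether cultures were separate. KO replicates 2 and 3 of day 0 differ little (chi-square per gene 2.67, log2 correlation 0.993), against 385.9 and 465.9 for replicate 1 with each of them, which leaves open whether these 2 came from separate cultures.

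Genes of the 2-cell-like state, a rare state of embryonic stem cells that resembles the 2-cell embryo, were higher in KO than in WT at day 0: all 19 of 19 measured members had a fold change above 1, with a median log2 of 1.78. Usp17le (chromosome 7, 111916563 to 111925984), from a deubiquitinase family, went from 46.4 ± 22.9 to 204 ± 15.5 (log2 2.23, SE 0.43). Tmem92 (chromosome 11, 94638531 to 94693316), a membrane protein gene that marks this state, went from 99.99 ± 63.5 to 309 ± 28.5 (1.78, SE 0.41; SD, n = 3). Usp17lb (chromosome 7, 111988826 to 111991018) and Usp17la (chromosome 7, 112005530 to 112011181) were higher by 4.57 (SE 0.81) and 3.24 (SE 0.63) on the log2 scale. The list rose as a group (camera, adjusted p = 6.1e-19, or adjusted p = 0.0412 with an estimated correlation), with a median of 1.69 between shallow and 2.38 between deep libraries, each with a single library in 1 arm, and of 1.94 with a depth term (adjusted p = 1.5e-14). Of its members 11 passed when adjusted over the list alone and 0 over all genes. Over 20624 genes limma called 0 (788 at an unadjusted p under 0.05), edgeR 0 (601) and DESeq2 17 (8 higher, 9 lower). The 788 became 328 without WT replicate 2, 1477 without WT replicate 3, and 1945, 475 and 425 without KO replicates 1, 2 and 3. Copies of Usp17l, Zscan4, Mage and Xlr genes share reads, and the labels do not say how reads with several positions were placed, so values of single copies are uncertain.

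Multicopy germline genes of the X chromosome were also higher in KO at day 0, with 21 of 21 members above 0 and a median log2 of 1.79 (camera, adjusted p = 4.0e-11, or adjusted p = 0.0456 with an estimated correlation). Magea10 (X, 69627209 to 69632197), a cancer-testis antigen gene, went from 1.52 ± 2.63 to 32.4 ± 7.51 (4.21, SE 1.07), and Magea3 (X, 151383006 to 151384112) from 0.09 to 8.93 (3.02, SE 0.74). These 2 passed when adjusted over the list alone and 0 over all genes. A single read stands for 3.54 and 4.18 scaled reads in WT replicates 1 and 2 and for 0.28 in WT replicate 3. Both WT means lie below 1 read of a shallow WT library, so the size of these 2 log2 changes depends on depth and the pseudocount. The list median was 0.95 between shallow and 1.98 between deep libraries. Of all X-linked genes 656 of 822 were above 0, with a median of 0.42 against 0.17 for all genes (camera, adjusted p = 3.8e-05, or adjusted p = 0.564 with an estimated correlation). Over libraries X reached the smallest exact p, 0.1, but so did 7 of 19 autosomes, with medians of 0.14 to 0.30, so this value does not set X apart. Of the X-linked genes 44 (5.35%) were higher at an unadjusted p under 0.05, against 367 of 19796 others (1.85%; odds ratio 2.99, Fisher p = 2.9e-09, 2-sided). The odds ratio was 1.93 without WT replicate 1 and 1.95 without KO replicate 2. The X share of reads was 3.92, 4.00 and 4.87% in WT and 3.97, 5.04 and 5.10% in KO, so it moves with depth. With a term for depth the X median was 0.27.

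Neat1 and Malat1, abundant nuclear noncoding RNAs, were lower in KO at day 0 (-0.67 and -0.56), as were all 5 members of their list (camera, adjusted p = 0.0041, or adjusted p = 0.489 with an estimated correlation). Without WT replicate 2 the list gave 0.107, and without KO replicate 2 it gave 0.0543. Hox genes, which set body position, were higher for 34 of 39 members (median 0.70, adjusted p = 0.0070, or adjusted p = 0.566 with an estimated correlation), such as Hoxd11 from 6.80 to 32.3; the list gave 0.151 without WT replicate 1 and 0.0522 without KO replicate 1. Protocadherin beta genes, which encode cell adhesion proteins, were higher for 8 of 9 members (adjusted p = 0.0062, or adjusted p = 0.564 with an estimated correlation), and this was lost without KO replicate 1 (0.318). Primed epiblast genes were higher for 8 of 10 (adjusted p = 0.0499, or adjusted p = 0.320 with an estimated correlation), with Fgf5, an epiblast growth factor gene (chromosome 5, 98683203 to 98706052), from 7.08 to 21.9. This call ended without WT replicate 2 (0.184) or any KO library (0.0875, 0.078 and 0.0899). Germline genes were higher for 24 of 29 (adjusted p = 0.0499, or adjusted p = 0.859 with an estimated correlation), with Tex19.1, a transposon control gene, at 0.84. Rhox homeobox genes were higher for 10 of 10 (adjusted p = 0.0499, or adjusted p = 0.460 with an estimated correlation). Germline and Rhox both lost their calls without WT replicate 1 (0.381 and 0.142), WT replicate 3 (0.063 and 0.189), KO replicate 1 (0.195 and 0.0875), KO replicate 2 (0.0562 and 0.1) or KO replicate 3 (0.0899 and 0.106). In these 6 lists 0 members passed over all genes or over the list alone. With a term for depth the noncoding (0.160), Hox (0.0511), primed epiblast (0.157), germline (0.147) and Rhox (0.147) calls ended, and the protocadherin call ended without the libraries with background reads (0.432). RLE scaling ended the primed epiblast (0.0567), germline (0.0567) and Rhox calls (0.0663), and TMM scaling the germline (0.0508) and Rhox calls (0.0634). In the same order the medians were -0.37, 0.63, 2.04, 0.70, 0.63 and 0.53 between shallow libraries and -0.16, 0.32, 0.42, 0.18, 0.22 and 0.93 between deep ones. Naive pluripotency genes did not pass at day 0 (adjusted p = 0.214). The depth term also called lists that the main setting did not. Stress genes (camera, adjusted p = 0.0013, median -0.60) and proliferation genes (0.0251, median -0.25) were then lower in KO at day 0.

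Naive pluripotency genes, which are shut down as stem cells differentiate, were higher in KO than in WT at day 10: 28 of 28 members were above 0, with a median log2 of 1.09 against -0.26 for all genes. Tdh, the threonine dehydrogenase gene of mouse stem cells (chromosome 14, 64111184 to 64127929), was at 136 ± 100 in WT and 917 ± 128 in KO (2.97, SE 0.49). Klf2, a naive state transcription factor gene (chromosome 8, 74842961 to 74845553), was at 327 ± 238 and 1019 ± 304 (1.99, SE 0.55). Fgf4, a growth factor gene (chromosome 7, 152047291 to 152051148), was at 339 ± 163 and 810 ± 126, and Dppa4, a chromatin factor gene (chromosome 16, 48283848 to 48294405), at 149 ± 36.8 and 322 ± 64.7 (SD, n = 3). The list rose as a group (camera, adjusted p = 1.1e-24, or adjusted p = 0.105 with an estimated correlation). A split that mixed KO and WT libraries of day 10 also gave a low unadjusted camera p for this list, 2.7e-16, against 4.0e-26 for the real groups. Of its members 16 passed when adjusted over the list alone and 0 over all genes. limma called 0 genes (2462 at an unadjusted p under 0.05; 1451 without WT replicate 3, 1570 without KO replicate 2, 1588 without KO replicate 3), edgeR 0 (2074) and DESeq2 470 (131 higher, 339 lower).

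**Figure D2:**
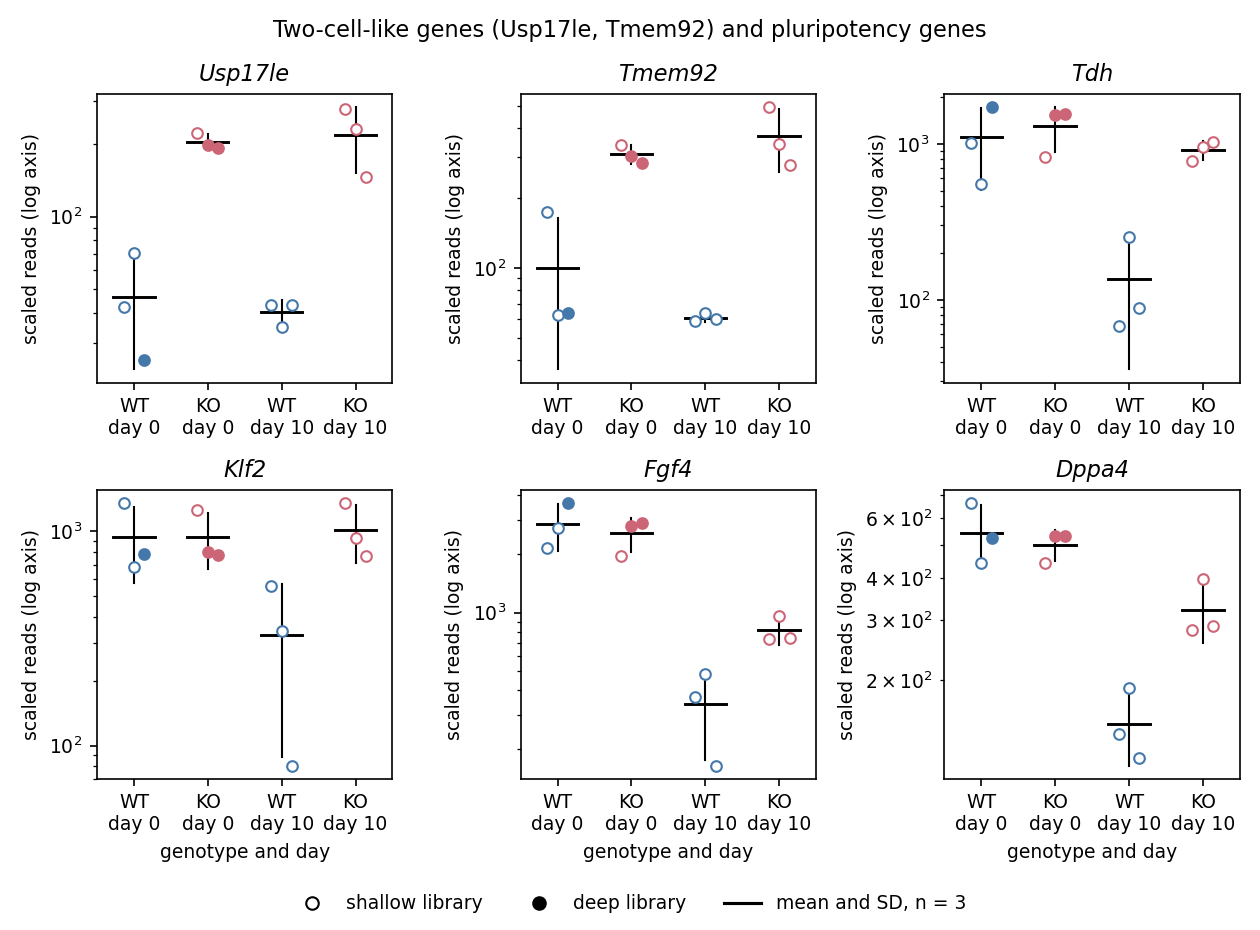
Scaled reads (log axis) of Usp17le, Tmem92, Tdh, Klf2, Fgf4 and Dppa4 in WT and KO at day 0 and day 10; points are libraries (open shallow, filled deep), lines are means and bars are SD with n = 3. Usp17le is higher in KO on both days (204 against 46.4 and 218 against 40.5), and Tdh at day 10 (917 against 136).

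2-cell-like genes were again higher in KO at day 10 for 16 of 19 members (median 1.53; camera, adjusted p = 9.7e-11, or adjusted p = 0.105 with an estimated correlation). Tmem92 went from 61.0 ± 2.63 to 372 ± 112 (2.55, SE 0.41) and Usp17le from 40.5 ± 4.72 to 218 ± 66.9 (2.36, SE 0.43); these 2 passed over the list alone and 0 over all genes. Members of the Usp17l and Zscan4 families had a median of 1.65 (10 of 10 above 0) and the 9 others of 0.75 (6 of 9 above 0). Zfp352, a zinc finger gene of the 2-cell stage, was at -0.65. Hox genes were higher for 32 of 39 (median 1.16, adjusted p = 2.1e-10, or adjusted p = 0.105 with an estimated correlation). Hoxb9, a trunk Hox gene (chromosome 11, 96132644 to 96137907), went from 18.5 ± 3.75 to 79.2 ± 21.4 and alone passed over the list, while Hoxb7 was at -1.48.

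Zfp57, which guards imprints, was at 372 in WT and 770 in KO at day 10, and 9 of 11 DNA methylation genes were above 0 (camera, adjusted p = 1.1e-04, or adjusted p = 0.332 with an estimated correlation), with Tdg, a repair glycosylase gene, at -0.63. Hand2, a heart and limb factor gene (chromosome 8, 59799780 to 59803314), was at 32.5 ± 42.3 and 170 ± 110, and 14 of 17 mesoderm genes were above 0 (adjusted p = 7.9e-04, or adjusted p = 0.441 with an estimated correlation); without WT replicate 1 this gave 0.251. Primed epiblast genes were higher for 8 of 10 (adjusted p = 0.0053, or adjusted p = 0.105 with an estimated correlation). Fibroblast genes were higher for 9 of 16 (adjusted p = 0.0085, or adjusted p = 0.488 with an estimated correlation), with Acta2, a smooth muscle actin gene, from 312 to 2317 and Dcn, a matrix proteoglycan gene, listed at 0 in KO. That call ended without WT replicate 1 (0.0945) or KO replicate 3 (0.053). Linker and core histone genes were higher for 13 of 14 (adjusted p = 2.6e-05, or adjusted p = 0.381 with an estimated correlation) and p53 targets for 14 of 17 (adjusted p = 4.7e-04, or adjusted p = 0.488 with an estimated correlation). Stress response genes were higher for 9 of 12 (adjusted p = 0.0101, or adjusted p = 0.488 with an estimated correlation) and proliferation genes for 10 of 15 (adjusted p = 0.0143, or adjusted p = 0.647 with an estimated correlation). All 4 of these calls ended without WT replicate 3 (0.131, 0.133, 0.772 and 0.962), which carries background reads, and the stress direction turned; proliferation also ended without KO replicate 2 (0.0531). Rhox genes were above 0 for 5 of 10 (adjusted p = 0.0496, or adjusted p = 0.354 with an estimated correlation). Rhox1 went from 4.59 to 32.1 and is the sole member in these 9 lists to pass over the list alone, with 0 passing over all genes. The Rhox list call ended with RLE (0.0965) or TMM scaling (0.0598) or a depth term (0.0728). It also ended without WT replicate 1 (0.0719), WT replicate 2 (0.171), KO replicate 2 (0.0902) or KO replicate 3 (0.115). Of the X-linked genes 37 (4.5%) were higher at an unadjusted p under 0.05, against 1.96% of others (odds ratio 2.36, Fisher p = 1.2e-05, 2-sided), and 74 (9.0%) were lower, against 9.92% (odds ratio 0.90, p = 0.438), with a median of -0.09 (exact p = 0.8 over libraries).

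**Figure D3:**
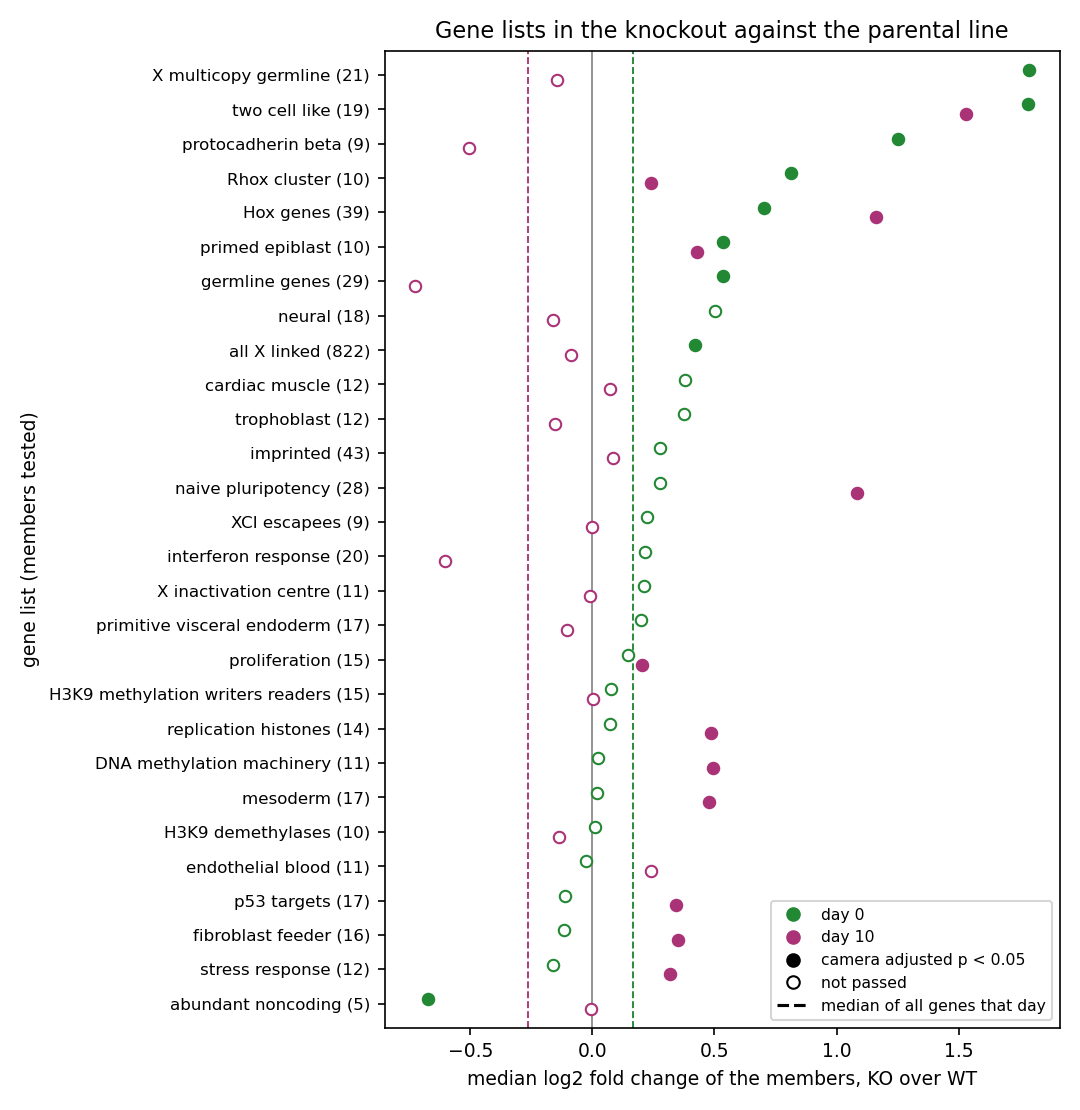
Median log2 fold change of KO over WT for 28 gene lists (horizontal axis) at day 0 (green) and day 10 (purple); filled points have a camera adjusted p under 0.05 and dashed lines are the median of all genes, 0.17 and -0.26. 2-cell-like genes lie right of the line on both days (1.78 and 1.53), and naive pluripotency genes at day 10 (1.09).

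Differentiation of WT cells raised Cdx2, a trophoblast and gut factor gene (chromosome 5, 148112476 to 148118825), from 0.38 to 255 ± 146 (7.41, SE 0.84, adjusted p = 2.1e-04). The imprinted noncoding RNA H19 (chromosome 7, 149761437 to 149764051) rose from 202 ± 67.7 to 24550 ± 11610 (6.88, adjusted p = 2.4e-06) and the growth factor gene Igf2 (chromosome 7, 149836673 to 149846940) from 44.3 to 1071. The actin gene Acta1 (chromosome 8, 126415658 to 126418675) and the carbonic anhydrase gene Car4 (chromosome 11, 84771256 to 84779556) rose by 7.11 and 6.19. Esrrb, a naive pluripotency factor gene (chromosome 12, 87702067 to 87862578), fell from 5827 ± 1280 to 755 ± 289, the adhesion gene Jam2 (chromosome 16, 84774368 to 84826620) from 2777 to 90.9 and osteopontin Spp1 (chromosome 5, 104864130 to 104870072) from 3714 to 133 (SD, n = 3). Fam25c and Sept1, a septin gene, fell to log2 changes of -5.90 and -5.55. limma called 911 genes (417 higher, 494 lower; 466 without WT replicate 3 of day 0, 466 without WT replicate 2 of day 10). edgeR called 1046 (507 higher, 539 lower) and DESeq2 1914. With RLE scaling the limma counts were 589 higher and 399 lower, since the median log2 of all genes moved from -0.20 to -0.01.

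Naive pluripotency genes fell as a group in WT, with 20 of 28 passing over all genes and 23 over the list alone (median -2.39; camera, adjusted p = 8.0e-22, or adjusted p = 0.0934 with an estimated correlation). Tcl1, an AKT coactivator gene (chromosome 12, 106454965 to 106460947), went from 973 to 50.9. Mesoderm genes rose for 8 of 17 (10 over the list alone, or adjusted p = 5.5e-13, or adjusted p = 0.0588 with an estimated correlation), with T, the Brachyury gene (chromosome 17, 8627288 to 8635361), from 11.8 ± 11.6 to 416 ± 28.1. The imprinted list rose (12 of 43, 16 over the list alone, adjusted p = 1.5e-11), as did primed epiblast (4 of 10, 6 alone, adjusted p = 2.8e-05) and trophoblast genes (5 of 12, 5 alone, adjusted p = 5.0e-05), and these 3 held with an estimated correlation (0.0187, 0.0187 and 0.0435). Germline genes fell for 7 of 29 (9 over the list alone, adjusted p = 4.8e-05, or adjusted p = 0.321 with an estimated correlation). Histone genes were higher for 14 of 14 with 0 passing (adjusted p = 4.8e-04, or adjusted p = 0.466 with an estimated correlation; 0.0665 without WT replicate 1 of day 10). Visceral endoderm genes rose for 2 and fell for 1 (6 and 3 over the list alone, adjusted p = 0.0096, or adjusted p = 0.466 with an estimated correlation). Hox genes rose as a group with 0 passing (adjusted p = 0.0091, or adjusted p = 0.472 with an estimated correlation; 0.0999 without WT replicate 2 of day 10).

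Neural genes fell for 3 members in WT, such as the microtubule regulator gene Stmn2 at -2.72 (4 over the list alone, adjusted p = 0.0142, or adjusted p = 0.244 with an estimated correlation). DNA methylation genes fell for 3, the demethylase genes Tet1 and Tet2 and the imprint guard Zfp57, at -2.23, -2.32 and -2.85 (4 members over the list alone, adjusted p = 0.0144, or adjusted p = 0.472 with an estimated correlation; 0.358 without WT replicate 3 of day 10). The stress list fell, with the glutathione gene Chac1 at -3.23 (1 member, 4 over the list alone, adjusted p = 0.0142, or adjusted p = 0.641 with an estimated correlation). That list gave 0.110 without WT replicate 2 of day 0, 0.0682 without WT replicate 3 of day 0 and 0.786 without WT replicate 3 of day 10. With a depth term it gave 0.0761. Of the X-linked genes 49 (5.96%) fell and 14 rose (70 and 18 over the list alone), against 445 of the others falling (2.25%; odds ratio 2.76, Fisher p = 6.1e-09, 2-sided). As a list they fell (adjusted p = 0.0142, or adjusted p = 0.641 with an estimated correlation), which was lost without WT replicate 3 of day 0 (0.0756) or WT replicate 1 of day 10 (0.0696).

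Differentiation of KO cells raised the keratin genes Krt8 (chromosome 15, 101827142 to 101834773) from 17.2 ± 2.35 to 3175 ± 676 (7.43, SE 0.36, adjusted p = 1.1e-07) and Krt18 (chromosome 15, 101858647 to 101862457) from 36.5 to 3938 ± 837 (SD, n = 3). Acta1 rose from 2.21 to 817 ± 261 (8.26), Foxf1, a lateral mesoderm factor gene (chromosome 8, 123608286 to 123612054), from 3.12 to 388, and H19 from 279 ± 132 to 27210 ± 4596. The lowest log2 changes were those of long genes such as Lmo3, a LIM protein gene (chromosome 6, 138313002 to 138530489), and Kcnip4, a channel regulator gene (chromosome 5, 48780742 to 49676898), which went from 237 ± 264 and 637 ± 770 to a value listed at 0 and 5.41. Their day 0 values are highest in KO replicate 1 (541.7 and 1525.6), which carries background reads. limma called 1834 genes (502 higher, 1332 lower), edgeR 1046 (551 higher, 495 lower) and DESeq2 3153. With RLE scaling the limma counts were 785 higher and 700 lower, as the median log2 of all genes moved from -0.68 to -0.41. Leaving out each library in turn gave 2889, 304 and 285 (KO replicates 1, 2 and 3 of day 0) and 502, 298 and 199 (KO replicates 1, 2 and 3 of day 10). In both WT and KO 497 genes passed in the same direction (255 higher, 242 lower) and 0 in opposite directions; chance overlap would give 10.15 and 31.9.

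Mesoderm genes rose as a group in KO, with 8 of 17 passing over all genes and 11 over the list alone (camera, adjusted p = 1.1e-18, or adjusted p = 0.0204 with an estimated correlation). T went from 8.38 ± 3.53 to 419 ± 124 and Hand1, a placenta and heart factor gene (chromosome 11, 57642215 to 57645649), from 10.1 to 704. Imprinted genes rose for 13 of 43 and fell for 2 (17 and 4 over the list alone, adjusted p = 9.5e-13), primed epiblast genes rose for 4 of 10 (6 alone, adjusted p = 5.0e-07) and trophoblast genes for 5 of 12 (5 alone, adjusted p = 5.0e-06); these held with an estimated correlation (0.0102, 0.0102 and 0.0204). Naive pluripotency genes fell for 12 of 28, with Esrrb from 5550 ± 1192 to 1395 ± 335 and Tcl1 from 963 to 129 (17 over the list alone, adjusted p = 2.5e-04, or adjusted p = 0.474 with an estimated correlation; 0.114 with a depth term). Germline genes fell for 15 of 29, with the germ cell RNA-binding gene Dazl (chromosome 17, 50418718 to 50432945) from 232 to 12.9 (22 over the list alone, adjusted p = 2.1e-06, or adjusted p = 0.185 with an estimated correlation). Multicopy germline genes of the X fell for 7 of 21 (12 over the list alone, adjusted p = 1.4e-04, or adjusted p = 0.163 with an estimated correlation).

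Hox genes rose for 3 members in KO, Hoxb8, Hoxa11 and Hoxb1 (5 over the list alone, adjusted p = 2.3e-08, or adjusted p = 0.121 with an estimated correlation), and histone genes for 3 members such as the linker histone gene Hist1h1c at 1.39 (9 over the list alone, adjusted p = 2.2e-11, or adjusted p = 0.117 with an estimated correlation). p53 targets were higher with 0 passing (adjusted p = 2.4e-04, or adjusted p = 0.437 with an estimated correlation). Fibroblast genes rose for 3, such as Acta2 at 4.25, and fell for 2 (4 and 3 over the list alone, adjusted p = 5.0e-04, or adjusted p = 0.394 with an estimated correlation). Visceral endoderm genes rose for 3 and fell for 1 (5 and 2 over the list alone, adjusted p = 0.0120, or adjusted p = 0.437 with an estimated correlation). The test called that list upward although its median of -0.23 and mean of -0.10 lie below 0, and it gave 0.0528 without KO replicate 3 of day 10. Neural genes fell for 3 of the list, such as Stmn2 at -2.66 (8 over the list alone, adjusted p = 0.0319, or adjusted p = 0.257 with an estimated correlation; 0.0595 without KO replicate 3 of day 10). Of the X-linked genes 116 (14.1%) fell and 13 rose (169 and 17 over the list alone), against 6.14% of the others falling (odds ratio 2.51, Fisher p = 1.1e-15, 2-sided); as a list they fell (adjusted p = 9.8e-04, or adjusted p = 0.474 with an estimated correlation). That odds ratio was 0.58 (Fisher exact p = 0.778) without KO replicate 3 of day 10, 0.77 (p = 0.821) without KO replicate 2 of day 0 and 1.06 (p = 0.813) without KO replicate 3 of day 0. All deep libraries are of day 0, and with a depth term the fibroblast, visceral endoderm, neural and X-linked calls ended (adjusted p = 0.298, 0.147, 0.117 and 0.117).

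Naive pluripotency genes changed less in KO than in WT: the difference of the changes was above 0 for 26 of 28 members (median 0.78; camera, adjusted p = 1.8e-13, or adjusted p = 0.725 with an estimated correlation). Tdh was at 2.64 (SE 0.69), the stem cell marker gene Dppa5a at 2.15, Fgf4 at 1.52 and Dppa4 at 1.22 (n = 3 per group), and 0 members passed over the list alone. Multicopy germline genes of the X were below 0 (median -1.94, adjusted p = 0.0167, or adjusted p = 0.725 with an estimated correlation), and this ended without WT replicate 1 (0.0537), KO replicate 2 (0.224) or KO replicate 3 (0.232) of day 0. Histone (5.2e-04), p53 target (0.0014), DNA methylation (0.0014), Hox (0.0027) and stress genes (0.0029) had positive differences by camera adjusted p. So had fibroblast (0.0115) and mesoderm genes (0.0253), and all of these calls were lost with an estimated correlation (adjusted p = 0.725 in each). Without WT replicate 3 of day 10 the histone, p53, DNA methylation and stress calls ended (0.112, 0.0904, 0.0693 and 0.518), and without WT replicate 1 of day 10 the Hox, fibroblast and mesoderm calls (0.077, 0.0979 and 0.671). Leaving out a day 0 library ended the p53 call (0.172, WT replicate 2), the stress call (0.101, KO replicate 1), the fibroblast call (0.596, WT replicate 1; 0.0843, KO replicate 2; 0.0853, KO replicate 3) and the mesoderm call (0.255, WT replicate 2; 0.0511, KO replicate 2). The mesoderm call also ended without KO replicate 1 of day 10 (0.0642) and the fibroblast call without KO replicate 3 of day 10 (0.0525). With a depth term the X multicopy germline, mesoderm and fibroblast calls ended (0.139, 0.124 and 0.392), and proliferation genes were called upward (0.0019). limma called 0 genes (1795 at an unadjusted p under 0.05; 2848 without WT replicate 1 and 1038 without WT replicate 3 of day 10), edgeR 0 (1543) and DESeq2 68 (12 higher, 56 lower). Exchanging KO and WT libraries within each day gave as many called lists as the real 9 in 36 of 100 splits. For naive pluripotency genes some of these splits gave a lower unadjusted camera p (down to 1.8e-24) than the real 6.4e-15.

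Xist, the noncoding RNA that silences the X chromosome it is made from (X, 100655712 to 100678572), rose in both lines. WT went from 538 ± 273 to 5826 ± 1270 (log2 3.52, SE 0.32, adjusted p = 5.2e-05) and KO from 674 ± 69.0 to 4089 ± 620 (2.59, SE 0.32, adjusted p = 6.7e-04; SD, n = 3). Differences between KO and WT did not pass (exact p = 0.4 at day 0 and 0.2 at day 10), nor did the difference of the changes (-0.93, SE 0.46, adjusted p = 0.580). Tsix, the antisense repressor of Xist (X, 100626856 to 100680296), fell in KO (-1.42, adjusted p = 0.0423 in limma, 0.0845 in edgeR) and was at -1.25 in WT (adjusted p = 0.101). Its span covers that of Xist and the strand of the libraries is not stated, so both values are uncertain. The Xist activator genes Jpx, Ftx and Rlim did not pass in any comparison (0.20, 0.23 and 0.21 at day 0; 0.26, -0.74 and 0.25 at day 10). X-inactivation center genes as a list had a lowest adjusted p of 0.0692 (WT differentiation), and 0.0307 without WT replicate 1 of day 0. The other lists not called in any comparison with all libraries and the authors' scaling had lowest adjusted p of 0.244 (escape genes), 0.0503 (H3K9 writers and readers), 0.779 (H3K9 demethylases), 0.134 (cardiac), 0.282 (endothelial) and 0.139 (interferon). Other settings did call some of them, but an estimated correlation called none. H3K9 writers and readers were called upward in KO differentiation and in the difference of the changes with a depth term (0.0154 and 0.0257) or RLE scaling (0.0304 and 0.0328), and at day 10 with RLE scaling (0.0367) or without WT replicate 2 (0.0174). Leaving out KO replicate 2 or 3 of day 0 also called them in KO differentiation (0.0423 and 0.0458) and in the difference (0.0254 and 0.0263). The difference was further called without WT replicate 2 of day 0 (0.0133), WT replicate 2 of day 10 (0.0131) or KO replicate 1 of day 10 (0.0468). Cardiac and endothelial genes were called upward at day 10 without WT replicate 3 (0.0183 and 0.0219). Interferon genes were called downward at day 0 without WT replicate 3 (0.0294) or KO replicate 1 (0.0343), and upward on differentiation of WT without WT replicate 1 of day 0 (0.0403). On differentiation of KO, leaving out KO replicate 1 of day 0 called cardiac (0.0453) and interferon genes (0.0205) upward.

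X-linked reads of the mus allele, taken here as the Mus musculus copy of the hybrid line, were a smaller share in each day 10 library than in every day 0 library of the same line. At day 0 they were 51.0% (Wilson 95% interval 50.3 to 51.6), 49.9% (49.1 to 50.7) and 48.4% (48.2 to 48.6) in WT and 50.3% (49.7 to 51.0), 47.7% (47.5 to 47.9) and 47.6% (47.4 to 47.8) in KO. At day 10 they were 25.2% (24.5 to 25.9), 25.1% (24.6 to 25.7) and 32.8% (32.2 to 33.4) in WT and 33.5% (32.7 to 34.3), 32.8% (32.2 to 33.5) and 30.2% (29.6 to 30.9) in KO. Intervals and floors cover counting error only. The change was -22.0 points in WT and -16.4 points in KO (exact p = 0.1 in each). At day 10 KO stood 4.46 points above WT (exact p = 0.2), and 7.01 points without WT replicate 3 (exact p = 0.1). These shares include Xist, and without it the day 10 difference was 5.19 points (exact p = 0.2). At day 0 KO stood at -1.20 points (exact p = 0.3). The difference of the changes was 5.66 points (exact p = 0.09).

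**Figure D4:**
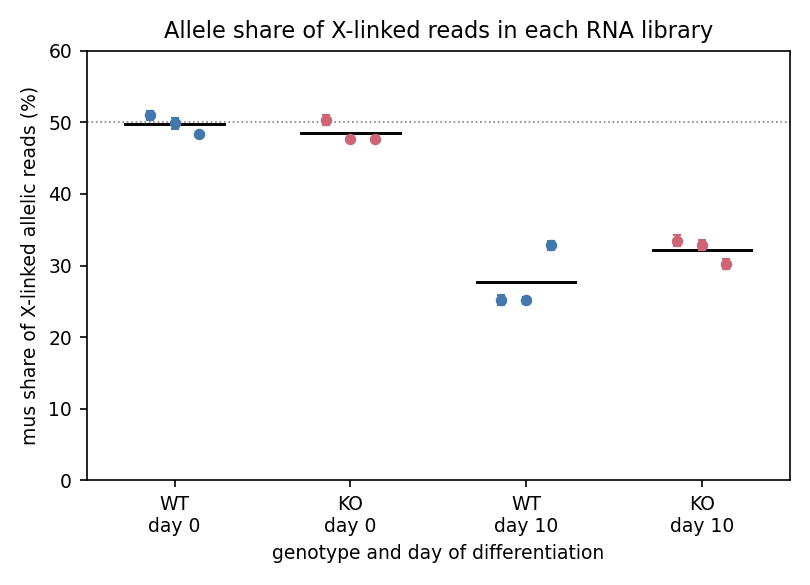
Percent of X-linked allelic reads from the mus allele in WT and KO at day 0 and day 10; points are libraries, bars are Wilson 95% intervals of the counts, lines are means of n = 3 and the dotted line is 50. The means are 49.8 and 48.6 at day 0 and 27.7 in WT and 32.2 in KO at day 10.

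Flna, an actin crosslinker gene (X, 71468800 to 71491873), went from 50.9 ± 5.63% to 11.2 ± 2.94% mus in WT (SD, n = 3; edgeR, adjusted p = 5.3e-05), and Med12, a Mediator kinase module gene (X, 98469430 to 98494273), from 51.8 to 6.0%. In WT 32 of 7802 genes changed their allele share, and 29 of these are X-linked, all toward cas. The creatine transporter gene Slc6a8 and the membrane linker gene Msn went from 54.6 to 16.5% and from 43.1 to 10.2%. The count was 9 without WT replicate 1, 13 without WT replicate 2 and 18 without WT replicate 3 of day 10, and 13 without WT replicate 2 of day 0. In KO 10 of 7791 genes changed, 4 of them X-linked: the angiomotin gene Amot (44.4 to 4.41%), the glycolysis gene Pgk1 (42.9 to 4.71%), the glypican gene Gpc3 (43.5 to 13.4%) and Flna (51.0 to 23.1%). Leaving out KO libraries gave 37, 3 and 5 (replicates 1, 2 and 3 of day 0) and 5, 4 and 4 (replicates 1, 2 and 3 of day 10). Thbs1, a thrombospondin gene on chromosome 2, moved in both lines (26.9 to 97.2% and 33.8 to 93.7%), and Col1a1 on chromosome 11 in KO (90.65 to 35.8%). Both are among the genes raised at day 0 in the first replicates of WT and KO. RNA from cells of another source may therefore enter their day 0 shares. Between KO and WT 0 genes changed by edgeR at day 0 (258 of 8653 at an unadjusted p under 0.05; 8 passed without WT replicate 3) and 0 at day 10 (313 of 7666). Over 281 X-linked genes the median at day 10 was 25% in WT and 30.6% in KO, with 197 of 281 higher in KO. Xist reads were 95 to 100% mus in every library. Genes known to escape X inactivation did not all keep their share. Between day 0 and day 10 the histone demethylase gene Kdm6a went from 51.1 to 44.1% in WT and from 53.1 to 50.6% in KO, but the demethylase gene Kdm5c from 50.5 to 30.4% and from 49.9 to 36.4%, and the helicase gene Ddx3x from 52.3 to 33.3% and from 48.2 to 40.6%.

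H3K9ac at promoters of naive pluripotency genes was present for 24 of 28 in WT and KO at day 0, and for 24 in WT and 19 in KO at day 10. Mesoderm promoters carried a peak for 13 of 17 in WT and 1 in KO at day 0, and for 12 and 11 at day 10. Acta1, H19, Krt8 and Car4 had a promoter peak in both lines only at day 10, Cdx2 and T only in KO at day 10, and Usp17le and Tmem92 in no sample. There is 1 peak list per group, so differences between groups carry no replicate error. The lists hold 63043 (WT) and 37696 (KO) peaks at day 0 and 37308 and 51497 at day 10, and 49.87, 40.08, 50.96 and 52.28% of 23952 promoters. Most of these peaks are weak. With a -log10 q of at least 5 the promoter shares were 0.28, 1.6, 9.67 and 10.68%, so at day 0 KO then stood above WT. Of WT peaks 19.75% (19.4 to 20.1) overlapped a KO peak at day 0, and 33.2% of KO peaks a WT peak; at day 10 these were 37.4 and 27.2%. Between the days 22.3% of day 0 and 37.4% of day 10 peaks overlapped in WT, and 30.04 and 21.9% in KO. Genes with a promoter peak in WT alone at day 0 had a median log2 of 0.00 for KO over WT, below each of 10000 matched random lists (their median 0.17). Genes with a peak in KO alone had 0.18, above 99.19% of such lists, but genes with no peak in either line had a higher median, 0.46, above all such lists, and genes with a peak in both had 0.08, below each. At day 10 the medians were -0.53 (WT alone, above 10.24% of random lists), -0.54 (KO alone, above 2.83%), -0.03 (both, above all) and -1.12 (no peak, below each). The libraries with background reads, KO replicate 1 of day 0 and WT replicate 3 of day 10, lie on opposite sides of these comparisons. The medians were not computed without them, so background reads and an effect of G9a cannot be told apart in these classes.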

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

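The tests of explanations and the counts over splits in this part were chosen after the results they bear on had been seen; the gene list tests were planned.

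Naive pluripotency genes dropped less on differentiation in the knockout than in WT, by a test of the difference of the changes (camera, adjusted p = 1.8e-13, or adjusted p = 0.725 with an estimated correlation, 26 of 28 members above 0, n = 3 per group). The same test set apart histone genes (5.2e-04), DNA methylation genes (0.0014), p53 targets (0.0014), Hox genes (0.0027), stress genes (0.0029), fibroblast genes (0.0115), X-linked multicopy germline genes (0.0167) and mesoderm genes (0.0253). All 8 of these calls are also lost with an estimated correlation (adjusted p = 0.725 in each), and each of them ends when 1 library is left out: histone, DNA methylation, p53 and stress genes without WT replicate 3 of day 10 (0.112, 0.0693, 0.0904 and 0.518), Hox, fibroblast and mesoderm genes without WT replicate 1 of day 10 (0.077, 0.0979 and 0.671), and the X-linked list without knockout replicate 3 of day 0 (0.232). The lists stand here because the preset test of the difference passed. Exchanging knockout and WT libraries within each day gave as many lists as the real 9 in 36 of 100 splits (highest other 14), so chance cannot be excluded for the number of lists. For naive pluripotency genes the unadjusted camera p was 6.4e-15 in the real split, and some exchanged splits went lower, down to 1.8e-24. The splits therefore cannot exclude chance for that list either. These splits are not free of real differences: 8 keep the real groups of day 0 and mix only day 10 (7 of them reach 9 lists, at most 14), and 11 set the deep against the shallow libraries of day 0 (2 reach 9). Of the 80 that mix day 0 in another way 26 reach 9 lists, at most 13. For X-linked genes 45 of 100 splits had an odds ratio as high as the real 1.53 (highest other 4.66). For genes the real count by limma was 0 (1795 at an unadjusted p under 0.05, 0 by edgeR, 68 by DESeq2). All 100 of 100 splits reach a count of 0 by construction, so this says nothing about chance. The highest other was 2613, in a split that sets deep against shallow libraries at day 0 and so points to a structure of the samples.

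H3K9ac peaks also lie on the sequence named rDNA, which no comparison uses: 7 in WT and 8 in the knockout at day 0, 2 and 4 at day 10. They stand here as signal in data outside the comparisons, and their highest fold enrichments are 2.25, 3.36, 1.94 and 1.91. No explanation was tested for them.

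Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. Genes past the threshold numbered 0, 0, 911 and 1834 in the real splits (knockout against WT at day 0 and day 10, differentiation of WT and of the knockout), with 3379, 0, 0 and 0 as the highest other, and 10, 10, 1 and 1 splits reached the real count. Here and for allele shares below, a real count of 0 is reached by every split by construction. Gene lists numbered 9, 12, 13 and 14, with 7, 11, 10 and 13 as the highest other (1 split each). For naive pluripotency genes at day 10 the unadjusted camera p was 4.0e-26 in the real split and 2.7e-16 in the lowest other. For 2-cell-like genes these were 2.2e-20 and 3.4e-10 at day 0, and 7.0e-12 and 1.0e-08 at day 10. Mixed groups thus also reach very low camera p values at the preset correlation. X-linked odds ratios at an unadjusted p under 0.05 were 2.99, 2.36, 2.56 and 2.03, with 1.9, 3.9, 1.72 and 1.56 as the highest other (1, 2, 1 and 1 splits). Genes with a changed allele share numbered 0, 0, 32 and 10, with 563, 0, 0 and 0 as the highest other (10, 10, 1 and 1 splits). The day 0 split with 3379 genes and 563 allele genes sets WT replicates 1 and 2 and knockout replicate 1 against the 3 deep libraries, so it points to a structure of the samples, their depth and Rn45s share. Within depth classes, with 1 knockout library in the shallow and 1 WT library in the deep class, the day 0 median of the 2-cell-like list is 1.69 and 2.38, and Ehmt2 is at -0.90 and -1.75.

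X-linked reads of the mus allele were a larger share in the knockout at day 10, by 4.46 points (exact p = 0.2; 7.01 without WT replicate 3). The day 10 library with background reads is WT replicate 3, and the difference was larger without it, which argues against background as its cause. Background reads would weigh least on the X-linked genes with the most reads per kb, where the difference was 5.82 points. With the background in WT, a larger difference there could be foreseen, so that test adds little. Chromosomes 5, 7, 9 and 13 differed by 0.11 points (exact p = 0.4), which argues against a shift of allele assignment in whole libraries. Cells left undifferentiated may account for it: pluripotency gene levels left at day 10 (19.5 ± 6.66% of day 0 in WT, 37.0 ± 7.4% in the knockout, SD, n = 3) predict 4.34 points. These genes had already been seen to be higher in the knockout at day 10. A prediction above 0 followed from that result, so it does not test this explanation. In knockout replicates 1, 2 and 3 the levels left were 35.4, 45.05 and 30.5%, and the shares 33.5, 32.8 and 30.2%. WT replicate 3 has the lowest level left (11.8%) and the highest share in WT (32.8%), but it is a library with background reads. Over the X-linked genes with the most reads per kb its share was 29.6%, against 26.2 and 27.6% in WT replicates 1 and 2. The mesoderm list is not lower in the knockout (median 0.48). Undifferentiated cells and slower silencing of the X in each cell cannot be told apart, because each library averages a whole culture.

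2-cell-like genes were higher in the knockout at day 0 in 19 of 19 members (median 1.78). The median was 1.99 without the 2 libraries with background reads and 1.62 over the 9 members outside the Usp17l and Zscan4 families. It was 1.94 with a depth term over all libraries (camera, adjusted p = 1.5e-14), while the 1.69 within shallow libraries rests on knockout replicate 1 alone and the 2.38 within deep ones on WT replicate 3 alone. These values argue against background reads, depth and reads shared among Usp17l and Zscan4 copies as the whole cause. Reads shared by copies of the 9 other members were not tested. Loss of G9a may raise these genes, a hypothesis found and tested on the same data, and a difference between clones or cultures apart from G9a stays open and was not tested.

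Collagen and other fibroblast genes were high at day 0 in WT replicate 1 and knockout replicate 1, with Col1a1 at 3996.6 and 924.7 against 47.8 to 91.9 in the other 4 libraries. RNA from cells of another source may account for it: Y-linked genes, which a female line lacks, had 28.3 and 11.9 CPM (reads scaled to depth), the lower of them 3.91 times the highest other library (57 and 26 reads). Differentiation of the line's own cells is argued against by alleles, since in the 13 of 61 raised genes where both alleles could be read the mus share in WT replicate 1 differs from day 10 by a median of 35 points, against 7.9 over 3442 other genes (11 of 13 differ by Fisher's exact test, 10 of them toward mus, while Thbs1 goes from 95.7% at day 10 to 29.3%). For Col1a1 and Thbs1 the gap from day 10 is not particular to the first replicates. Over all day 0 libraries their mus shares were 97.3% (SD 4.61) and 26.9% (SD 8.50) in WT, and 90.65% (SD 3.55) and 33.8% (SD 4.68) in the knockout. Depth is argued against by WT replicates 1 and 2, which are alike in depth and differ by a median log2 of 2.08 over the list. Of the list's 16 genes 14 are also above 1 in every other day 0 library, 0 are in another list, and the labels mention no feeder cells.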

How the results depend on the processing

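Some alternatives were chosen after seeing the data: edgeR on recovered reads, the depth term, TMM scaling, fits without the 2 libraries with background reads, medians within depth classes and the best covered X-linked genes. Of 415 comparisons of a main result with an alternative 332 were counted as the same, 69 moved, 8 were weaker, 4 stronger and 2 reversed. Of 1800 for the other gene lists 1580 were the same, 140 weaker, 73 stronger and 7 reversed, and of 7284 for named genes 6878 were the same, 249 weaker, 157 stronger and 0 reversed. Results counted as the same kept their side of the threshold or their size. A change of direction between values that both missed the threshold was also counted as the same. The 0 reversed therefore does not mean that every named gene kept its direction. Ehmt2 and the X-linked medians were judged by exact p, which cannot pass the threshold with so few libraries, so they could not change side. The cause was not tested for the values below, except where fewer libraries or genes enter by construction.

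Genes between knockout and WT at day 10 numbered 0 by limma (2462 at an unadjusted p under 0.05, 0 by edgeR) and 111 with a pseudocount of 0.1 (7 higher, 104 lower), 1 with only the compared groups in the fit, 7 with a depth term and 470 by DESeq2. DESeq2 called 17 at day 0 and 68 for the difference of the changes, where limma and edgeR called 0 (788 and 1795 at an unadjusted p under 0.05 in limma). Genes changed by differentiation of WT (911) numbered 372 with only the compared groups, 2141 without the background libraries, 1971 by edgeR without them, 1412 by edgeR with a depth term and 1914 by DESeq2. In the knockout (1834) they numbered 1054 with a pseudocount of 5, 4165 with only the compared groups, 2866 with a depth term, 5409 without the background libraries, 1046, 1079 (RLE) and 839 (no filter) by edgeR, 3775 by edgeR without the background libraries and 3153 by DESeq2. Leaving out each library in turn gave 466 to 1051 in WT and 199 (without knockout replicate 3 of day 10) to 2889 (without knockout replicate 1 of day 0) in the knockout.

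Gene lists past the threshold (9, 12, 13, 14 and 9) numbered 2, 0, 3, 4 and 0 with an estimated correlation, and the 9 for the difference of the changes ran from 5 (without WT replicate 3 of day 10) to 11 (without WT replicate 2 of day 10). Naive pluripotency genes gave an adjusted p of 0.105 at day 10, 0.0934 in WT and 0.474 in the knockout with an estimated correlation, and 0.114 in the knockout with a depth term. Proliferation genes reversed with a depth term at day 0 (0.0251) and in the knockout (0.01003), and without the background libraries at day 10 (0.890) and for the difference of the changes (0.0042). Stress genes reversed without the background libraries at day 10 (0.834) and for the difference (0.622), and leaving out libraries gave 6.4e-05 to 0.772 at day 10, the highest without WT replicate 3 with the direction turned. The day 0 median of 2-cell-like genes was 1.69 within shallow and 2.38 within deep libraries. The odds ratio of X-linked genes lowered in the knockout ran from 0.58 (without knockout replicate 3 of day 10) to 3.40 (without knockout replicate 1 of day 10).

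The mus share of X-linked reads changed by -16.4 points in the knockout, by -18.2 points without Xist and by -18.2 points as a median of gene shares. In WT these changes were -22.0, -24.55 and -25.2 points. At day 10 the knockout stood above WT by 4.46 points, by 5.19 points without Xist (exact p = 0.2) and by 6.375 points as a median of gene shares (exact p = 0.1). Genes with a changed allele share numbered 65 in the knockout without the background libraries (10 in all libraries). Leaving out each library gave 0 to 8 at day 0 (8 without WT replicate 3), 9 to 40 in WT (9 without WT replicate 1 of day 10, 40 without WT replicate 1 of day 0) and 3 to 37 in the knockout (3 without knockout replicate 2 of day 0, 37 without knockout replicate 1 of day 0).

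With replicate number as a block, changed allele shares numbered 5 at day 10, 82 in WT and 113 in the knockout, and genes by limma 0, 0, 850, 1612 and 0. With this block the primed epiblast, germline and Rhox calls at day 0 ended (0.058, 0.0624 and 0.0615), as did Rhox at day 10 (0.0525). H3K9 writers and readers were then called upward for the difference of the changes (camera, adjusted p = 0.047). The numbers do not pair the samples: deviations of like-numbered WT and knockout libraries at day 0 correlate at 0.427, -0.11 and 0.579, and those of the knockout days at 0.102, 0.106 and 0.002.

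H3K9ac peaks of WT overlapped those of the knockout at day 0 for 19.75%, and for 72.8% with a -log10 q of at least 5, 9.91% with 50% reciprocal overlap, 61.7% at a fold of at least 4 and 29.4% with the same number of peaks. In that order the values were 66.4, 24.6, 72.9 and 36.1% at day 10, 68.2, 12.1, 69.3 and 33.3% between the days in WT, and 54.6, 15.8, 62.9 and 28.8% between the days in the knockout. These are shares of the WT list or of the day 0 list. Counted from the other list, the first setting gave 46.8, 64.3, 15.03 and 18.2% and the fold setting 41.3, 77.2, 19.2 and 27.7%, since the lists differ in length (497 peaks of WT at day 0 against 2249 at day 10 in the first setting). Genes with a promoter peak in WT alone or in the knockout alone at day 10 had medians above 1.82 and 0.65% of random lists with promoters of 2 kb either side, and above 100 and 99.97% with a -log10 q of at least 5. At day 0 that stricter threshold gave 38.52% (WT alone), 83.64% (knockout alone) and 83.82% (no peak).

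No test varied depth alone; the shallow libraries hold 2081129 to 4220140 reads each. At the spread of these libraries simulated 4-fold changes were recovered in 4% (day 0) and 11% (day 10) of genes by limma, so counts of 0 leave most changes of that size unseen. At the same depths and 0.1 of the dispersion 100% were recovered, so the spread between libraries limits the counts.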

Other observations

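Hox promoters carried an H3K9ac peak in 23 of 39 genes in WT at day 0, 8 in the knockout at day 0, 10 in WT and 14 in the knockout at day 10. Fibroblast promoters did so in 3, 1, 4 and 8 of 16, trophoblast promoters in 3, 1, 7 and 7 of 12, interferon promoters in 4, 3, 8 and 11 of 20 and proliferation promoters in 15 of 15 in all 4 samples. Of the 2-cell-like promoters 1 of 20 carried a peak, in the knockout at day 0. The lists have median peak widths of 678, 648, 767 and 699 bases and cover 61.2, 34.6, 41.1 and 50.1 Mb, and 497, 771, 2249 and 2330 peaks reach a -log10 q of 5.

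Autosomes differ in how many of the genes covered by allelic reads carry both alleles: 97.9% on chromosome 13 (501 of 512 covered genes), 89.6% on 9, 82.8% on 7 and 78.8% on 5, 59.2% on 8, 44.9% on 2, 42.4% on 11, 25.1% on 6 and 4.62 to 9.15% on the other 11. Among genes with both alleles the median mus share is 35.2% on chromosome 8 (436 genes) and 37.7% on chromosome 6 (173 genes), and 50.8 to 51.8% on chromosomes 2, 5, 7, 9, 11 and 13. Rlim, which encodes a ubiquitin ligase of the X-inactivation center, had a mus share of 36.6% in WT and 32.7% in the knockout at day 0 and 11.0 and 17.9% at day 10. In the same order (WT and knockout at day 0, then at day 10) the escape genes Eif2s3x, Pbdc1, Shroom4 and Mid1 stood at 45.6, 41.7, 30.8 and 42.1%, at 43.3, 48.0, 25 and 35.0%, at 54.8, 51.1, 30.4 and 22.4% and at 31.5, 37.4, 15.9 and 5.37%, and Car5b, with 14 to 70 allelic reads, at 45.3, 41.4, 17.7 and 0%.

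With each library thinned to 1500000 reads, 21.7 and 22.3% of 1459 olfactory and vomeronasal receptor genes were detected in knockout replicate 1 of day 0 and WT replicate 3 of day 10, and 1.17 to 10.8% in the others. Rmrp, a small RNA gene of RNase MRP, stood at 1590 to 1763 scaled reads in the 3 deep libraries.

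The p-values deposited by the authors, adjusted here over 24016 genes, call 4 genes higher and 0 lower in the knockout at day 0 (785 at an unadjusted p under 0.05; limma 0, edgeR 0) and 43 higher and 243 lower at day 10. The median span of those 243 genes is 349.7 kb, against 14.12 kb for all genes. On differentiation they call 355 higher and 220 lower in WT and 742 higher and 3856 lower in the knockout.

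Of the input samples 2 have a title and characteristics that name different days; the files give no values for them.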
